A study of Mus musculus with 16 samples.

How the data were processed

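The samples were 16 two-colour hybridisations of liver poly(A) RNA on GEM 2.03 cDNA arrays, 2 for each of 8 female APOE3-Leiden mice fed cafestol and kahweol in a Western-type diet (fat 15 g and cholesterol 0.25 g per 100 g), with control-diet liver RNA in Cy3 and the treated liver in Cy5, per the labels. There were 0 arrays with the dyes swapped. The authors deposited log2 ratios of the 2 channels. Normalization, background treatment, the reason for blank values and the direction of the ratio are not given in the sources used here. All of the 144660 values equalled plus or minus log2 of a ratio with 1 decimal (within 0.01 of 10 times the ratio), so the smallest step from 0 was 0.138 and 31.8% of values were 0. Every array had a median of 0, so values were used as deposited, and 282 to 1502 probes per array were blank.

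Genes were named from the platform annotation of 2007, through Entrez identifiers in a RefSeq table (assembly GRCm38.p6, names only): 7407 probes had 1 gene symbol, 437 several and 1752 none, and 0 symbols of the annotation changed on updating. Probes of the same gene were averaged; the others stayed as unnamed probes. Of 8923 genes and unnamed probes, 575 with values in under 6 mice were left out, and 8348 (6355 named) were tested. Of 223 called genes with several probes, 37 had a probe mean of opposite sign.

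The 2 arrays of a mouse were averaged (n = 8), and the mean log2 ratio was tested against 0 with limma (version 3.58.1 in R 4.3.3; lmFit and eBayes, two-sided, Benjamini-Hochberg, adjusted p under 0.05). This p measures the spread among treated mice only. The comparison of SY and TP mice used the same model with 2 groups. The 35 gene lists, written before the data were examined, were tested with camera (preset correlation 0.01) when 5 or more genes were measured, 33 in all, adjusted over those lists. Because camera takes no blank values, its ranked-statistic form was run on the moderated statistics; on the 8059 genes and probes complete in 8 mice, the estimated correlation and fry were run. Named genes followed a rule fixed in advance: the 12 highest and 12 lowest called genes with the same sign in every measured mouse, up to 4 called members of each list (or 2 uncalled), a fixed set of bile acid, lipoprotein and detoxification genes, and the 5 highest and 5 lowest genes between SY and TP. Part of the fixed set is not reported here.

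On simulated data with the real gene spreads and the same rounding, with 200 genes changed, the diet test recovered 92.5% of 1.2-fold and 100% of 1.5-fold and 2-fold changes, with 16 calls among unchanged genes. The comparison of SY and TP recovered 26.9%, 89.6% and 100%, with 7 calls among unchanged genes. No spread of control mice, dye effect or correlation between genes was simulated. The calls among unchanged genes therefore say nothing about false calls from these sources. On complete rows the ranked-statistic form gave p = 3.67e-10 for the NRF2 list, the value of camera itself. Alternatives covered centring, scaling, quantile normalization, probes in place of genes, filters on blanks, robust moderation, leaving out each mouse, single arrays, arrays blocked by mouse, a minimum fold, each identifier series, and the spread of control mice; limma's scale normalization of ratios was run by median absolute value. Figures were drawn with matplotlib 3.10.9.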

Results

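Liver transcripts were measured in female APOE3-Leiden mice, which carry a human transgene for a variant of apolipoprotein E. The control was a Western-type diet, and the test diet added the coffee diterpenes cafestol (0.04% by weight) and kahweol (0.02%). The diets were fed for 4 weeks from 10 weeks of age to 7 control and 8 treated mice. Each of the 8 treated livers was hybridised on 2 cDNA arrays of 9596 probes, giving 16 arrays. The other channel of every array held liver RNA of the control diet, and no label names single control mice. The ratio against 0 is therefore the test, and the spread among control mice is left out of it. Between 8094 and 9314 probes had a value per array, and the number of mice and arrays limits the precision. The question was which liver genes respond to the diterpenes.

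The direction of the ratio is not given in the sources used here, so signs are printed as deposited. These diterpenes are known to induce glutathione S-transferases, of which Gstm1 and 3 relatives lay farthest below 0, and to lower Cyp7a1, which lay above 0, in rodents. Both would fall on these sides in a ratio of control over cafestol, but no test independent of these genes was made, and the direction stays unknown. In what follows, "the Gstm1 side" means a negative and "the Cyp7a1 side" a positive deposited log2 ratio.

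The 4 genes farthest from 0 were glutathione S-transferases, which conjugate foreign compounds. Gstm1, one of them (Entrez 14862), had a log2 ratio of -2.48 ± 0.23 (SD, n = 8 mice), a 5.59-fold difference (limma, adjusted p = 3.62e-10), and was negative in 8 of 8 mice. Its relatives Gstm6 (-1.93 ± 0.20), Gstp1 (-1.88 ± 0.16) and Gstm2 (-1.86 ± 0.27) followed. The cDNA probes of this family can also bind the transcripts of close paralogs. The same side held the microsomal epoxide hydrolase Ephx1 (-1.14 ± 0.16), D-amino acid oxidase Dao (-1.29 ± 0.12), Gsta2 (-1.11 ± 0.30) and carbonyl reductase Cbr1 (-0.91 ± 0.15). Also negative were Gsta4 (-0.85 ± 0.15), the heme-binding plasma protein Hpx (-0.82 ± 0.26), the siderophore-binding acute phase protein Lcn2 (-0.82 ± 0.49) and Ly6d (-0.89 ± 0.47). On the opposite side the highest named gene was Cyp7a1, the rate-limiting enzyme of bile acid synthesis (Entrez 13122), at 1.56 ± 0.38, a 2.95-fold difference (limma, adjusted p = 1.77e-06), positive in 8 of 8 mice.

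Other genes on the Cyp7a1 side were the methyltransferase Inmt (a 2.29-fold difference), the major urinary protein Mup9 (1.13 ± 0.84), uridine phosphorylase Upp2 (1.02 ± 0.51), the sulfotransferase Sult3a1 (0.92 ± 0.49) and ornithine aminotransferase Oat (0.84 ± 0.25). The group also held the steroid hydroxylase Cyp17a1 (0.83 ± 0.31), the lipogenic regulator Thrsp (0.78 ± 0.34), the chromatin remodeller Chd3 (0.76 ± 0.09), the tyrosine-degrading enzyme Hpd (0.73 ± 0.22) and regucalcin, Rgn (0.73 ± 0.27). The transcription factor Zic1 averaged 1.41 ± 0.83, but in the mouse SY518Z it read 2.20 on an array with code bl7 and 0.68 on an array with code c3z. These 24 genes were chosen as the 12 highest and 12 lowest called genes with the same sign in every measured mouse, and the highest adjusted p among them was 0.00193 (limma).

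**Figure D1:**
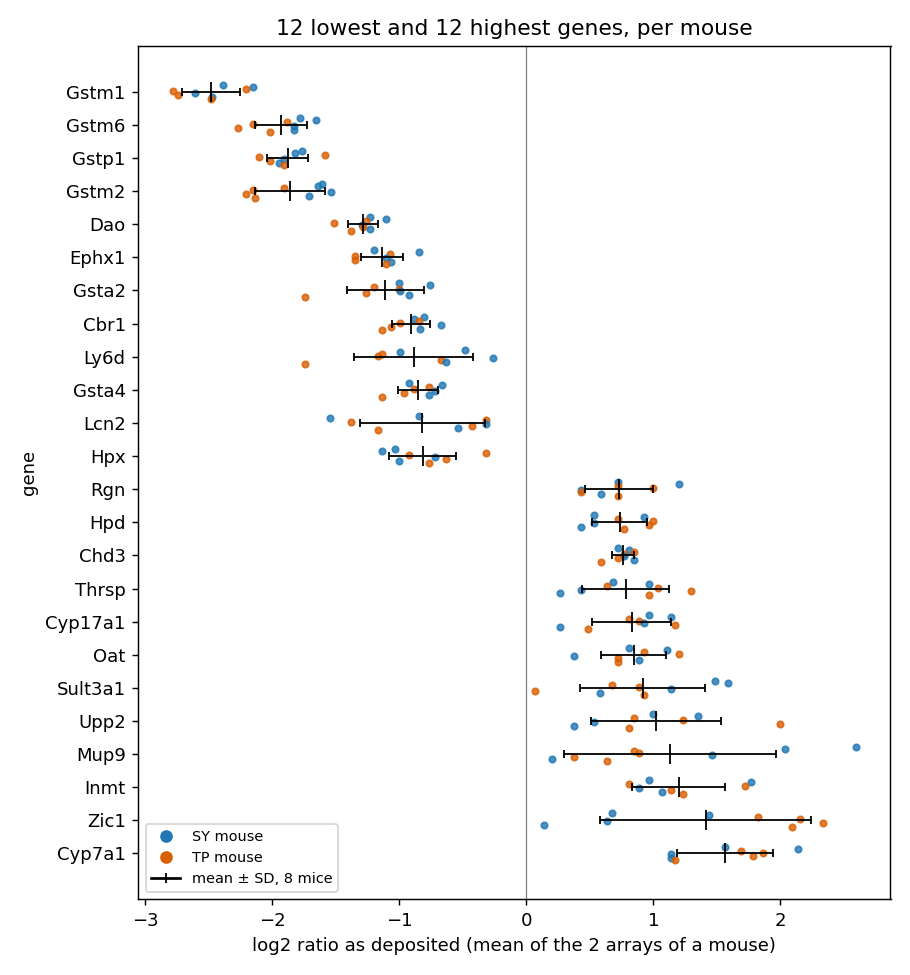
Deposited log2 ratio (x axis) of the 12 lowest and 12 highest named genes (y axis); points are the 8 mice, coloured by identifier series, and black bars are mean ± SD. Gstm1 averaged -2.48 and Cyp7a1 1.56, and genes were drawn only if all measured mice lay on the same side of 0.

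Of 8348 genes and unnamed probes tested, 3622 passed an adjusted p of 0.05, with 1503 positive and 2119 negative. Most differences were small: 63 of the 3622 reached 1.5-fold (24 positive, 39 negative), and 7 on each side reached 2-fold. Against a minimum difference of 1.2-fold 123 passed, and 1805 passed when the control RNA was treated as an equal mix of 7 mice that vary like the treated ones. All arrays carried the control in Cy3, so a dye effect specific to a gene would add to its ratio in every mouse.

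Most genes induced by the oxidative stress regulator NRF2 lay on the Gstm1 side. Of 24 measured, 18 were negative, 1 was positive and 5 did not pass (19 and 1 when adjusted over the list alone), and the median log2 ratio was -0.40 (camera, adjusted p = 5.95e-09; adjusted p = 0.408 with an estimated correlation). Beside the transferases, the fixed genes Gclc, the catalytic subunit of glutathione synthesis (-0.21 ± 0.20, limma adjusted p = 0.0108), and Nqo1, a quinone reductase (-0.20 ± 0.17, adjusted p = 0.00769), were negative in 6 of 8 mice each. Of 18 glutathione enzymes, 11 were negative, 4 positive and 3 not called, the same counts as when adjusted over the list alone (median -0.30, adjusted p = 0.00374; adjusted p = 0.657 with an estimated correlation). The glutathione list shares Gstm1, Gstm2, Gstp1, Gsta2, Gsta3, Gsta4, Gclm and Gclc with the NRF2 list, so these list results are not independent. Genes induced by the xenobiotic receptors PXR and CAR did not pass as a list (median 0.06, adjusted p = 0.296): 3 of 10 were positive, also when adjusted over the list alone, and 0 negative. The positive genes were Cyp2b9 (0.43 ± 0.43), Cyp2b10 (0.41 ± 0.36) and Fmo5 (0.35 ± 0.36, mean 0.069 in SY and 0.63 in TP mice). Cyp2b9 and Cyp2b10 were both highest in SY518Z (1.35 and 1.17), and may not be separate signals. Genes induced by the dioxin receptor AHR did not pass either (adjusted p = 0.961), with 2 of 5 negative and 1 positive on both adjustments. Cyp3a11, a PXR target fixed in advance, had values in 5 mice only, under the minimum of 6, and was not tested.

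Bile acid synthesis lay on the Cyp7a1 side. Of 9 measured genes 7 were positive, 1 negative and 1 not called (8 and 1 when adjusted over the list alone), with a median of 0.30 (camera, adjusted p = 9.41e-05; adjusted p = 0.458 with an estimated correlation). Positive members included the sterol carrier Scp2 (0.60 ± 0.19), the bile acid ligase Slc27a5 (0.50 ± 0.19) and the racemase Amacr (0.42 ± 0.20), while the oxysterol hydroxylase Cyp7b1 was at -0.17 ± 0.12. Bile acid and sterol transporters did not pass as a list (adjusted p = 0.997), with 2 of 8 positive, led by the sterol exporter Abcg5 (0.44 ± 0.16), and 2 negative on both adjustments. Genes induced by the bile acid receptor FXR split 2 against 2 of 8 on both adjustments (median -0.10, adjusted p = 0.819). The phospholipid transfer protein Pltp stood at -0.66 ± 0.15 and Fgf15 at -0.18 ± 0.07, against 0.23 ± 0.11 for fibrinogen Fgb and 0.21 ± 0.08 for syndecan Sdc1. Fgf15 lay close to the smallest step of the rounding, 0.138, and whether its signal exceeded background was not analysed here. The fixed genes Cyp8b1, Cyp27a1, Nr0b2, Slc10a1 and Abcb11 were not tested, having no single-gene probe or too few values.

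Genes of lipoprotein metabolism went both ways, with 6 of 16 negative, 2 positive and 8 not called (7 and 2 when adjusted over the list alone; median -0.08, adjusted p = 0.184). Negative members were Pltp, the high-density lipoprotein protein Apoa1 (-0.52 ± 0.35), lipoprotein lipase Lpl (-0.47 ± 0.24), Apoe (-0.41 ± 0.12), whose probe may also bind the transgene's transcript, the cholesterol-esterifying enzyme Lcat (-0.14 ± 0.10) and the sterol exporter Abca1 (-0.08 ± 0.07, limma adjusted p = 0.0485). Abca1 did not pass without SY521RL, SY518Z, TP4215, TP4168, TP4205 or TP4163 (adjusted p 0.0654 to 0.123). Apob, the main protein of low-density lipoprotein, was at 0.12 ± 0.12 (limma, adjusted p = 0.0302, positive in 5 of 8 mice), and did not pass without SY518Z, TP4215, TP4205 or TP4163 (adjusted p 0.0604 to 0.0854). Mttp, which loads lipid onto Apob, had -0.12 ± 0.16 (adjusted p = 0.0616), and passed without SY521RL (adjusted p = 0.0353) or SY524ROB+L (0.0296) and in TP mice alone (0.00665), while its mean in SY mice was 0.017. Cholesterol synthesis did not pass (adjusted p = 0.748), with 1 of 10 negative, the sterol isomerase Ebp (-0.39 ± 0.14), and 1 positive on both adjustments. In fatty acid synthesis (adjusted p = 0.265) 4 of 12 were positive, among them the glucose-responsive factor Mlxipl (0.67 ± 0.15) and the desaturase Fads2 (0.53 ± 0.26), and 2 negative, including malic enzyme Me1 (-0.43 ± 0.19), on both adjustments. Fatty acid oxidation had 8 of 21 positive, such as the thiolase Acaa2 (0.48 ± 0.15), and 3 negative, such as Ehhadh (-0.36 ± 0.36), on both adjustments. The list missed the threshold (adjusted p = 0.0799) and passed without TP4168 (0.0323) or TP4163 (0.0334), in SY mice alone (0.00713) and on the first arrays of the mice (0.0343).

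Complement and coagulation genes, urea cycle and amino acid genes, pericentral genes and female-biased genes lay on the Cyp7a1 side as lists. Of 26 complement and coagulation genes 15 were positive, 1 negative and 10 not called, the same when adjusted over the list alone (median 0.12, adjusted p = 1.65e-05; adjusted p = 0.458 with an estimated correlation). They were led by coagulation factor F13b (0.57 ± 0.11), complement Hc (0.48 ± 0.19), C8g (0.32 ± 0.18) and protein C, Proc (0.31 ± 0.09). Urea cycle and amino acid genes had 10 of 17 positive, such as proline dehydrogenase Prodh (0.52 ± 0.21), and 3 negative (12 and 3 when adjusted over the list alone; median 0.23, adjusted p = 0.000789; adjusted p = 0.458 with an estimated correlation). In the SY mice alone this list did not pass (adjusted p = 0.0549). Of the urea cycle itself it held only Otc (0.23 ± 0.08, called) and Cps1 (0.30 ± 0.46, not called). Its member farthest from 0, Dao (-1.29 ± 0.12), was negative. Pericentral hepatocyte genes, expressed around the central vein, had 7 of 11 positive and 0 negative on both adjustments (median 0.22, adjusted p = 4.33e-05; adjusted p = 0.458 with an estimated correlation), including the glutamate transporter Slc1a2 (0.58 ± 0.23). The pericentral genes Glul (0.16), Cyp1a2 (0.06), Axin2 (0.03) and Aldh1a1 (0.01) were not called. This list shares Cyp7a1 with bile acid synthesis and Oat with the amino acid genes, so these list results are not independent. Periportal genes split, 3 of 7 negative and 2 positive (3 and 3 when adjusted over the list alone; adjusted p = 0.748), with Cyp2f2 at -0.60 ± 0.38 and the growth factor binding protein Igfbp2 at 0.46 ± 0.18. Female-biased genes had 4 of 5 positive and 1 negative on both adjustments (median 0.43, adjusted p = 0.048; adjusted p = 0.458 with an estimated correlation). They did not pass without SY518Z (0.0594), TP4215 (0.0551) or SY524ROB+L (0.0617), nor in SY (0.132) or TP mice alone (0.161), on the second arrays (0.0522), after quantile normalization (0.0534) or scaling to a common SD (0.0535), or with a looser filter on blanks (0.0508).

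Several further lists did not pass. Acute phase proteins went both ways, 5 of 15 negative and 6 positive (adjusted p = 0.774), with the metallothioneins Mt1 (0.50 ± 0.45) and Mt2 (0.38 ± 0.41) opposite to Lcn2 and Hpx. Glucose metabolism had 5 of 11 positive, such as the gluconeogenic enzyme Pck1 (0.47 ± 0.41) and glycogen synthase Gys2 (0.47 ± 0.21), and 1 negative, Ugp2 at -0.46 ± 0.20 (adjusted p = 0.253; 5 and 2 when adjusted over the list alone). Oxidative phosphorylation had 11 of 32 negative, such as Ndufv3 (-0.33 ± 0.15), and 3 positive (adjusted p = 0.481). The circadian clock had 5 of 9 positive, such as Bhlhe40 (0.26 ± 0.21), and 1 negative (adjusted p = 0.3). Cytosolic and mitochondrial heat shock proteins had 2 of 11 negative and 1 positive, the co-chaperone Dnaja1 at 0.53 ± 0.37 (adjusted p = 0.984). Proteasome genes had 4 of 26 negative and 1 positive (2 and 0 when adjusted over the list alone; adjusted p = 0.784). Proliferation genes had 5 of 19 negative, such as Mcm6 (-0.25 ± 0.12), and 1 positive, Tyms at 0.25 ± 0.13 (adjusted p = 0.635). For acute phase, oxidative phosphorylation, clock, heat shock and proliferation genes the counts adjusted over the list alone were the same. Median and mean differed in sign for acute phase (0.07 and -0.05), cholesterol synthesis (0.05 and -0.02) and AHR-induced genes (0.06 and -0.01), none of which passed.

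Cytosolic ribosomal proteins and genes of endoplasmic reticulum stress and folding lay on the Gstm1 side, while the list of other heat shock proteins had not passed (adjusted p = 0.984). Of 24 cytosolic ribosomal proteins 18 were negative, 0 positive and 6 not called, the same when adjusted over the list alone (median -0.27, adjusted p = 1.02e-08; adjusted p = 0.458 with an estimated correlation). Among them were Rpl28 (-0.66 ± 0.18), Rplp1 (-0.59 ± 0.18), Rpl13 (-0.59 ± 0.13) and Rpl36a (-0.57 ± 0.12). Of 14 genes of endoplasmic reticulum stress and folding, 8 were negative and 0 positive, also when adjusted over the list alone (median -0.17, adjusted p = 0.00968; adjusted p = 0.657 with an estimated correlation). They included the chaperone Hspa5 (-0.66 ± 0.35), the secreted stress factor Manf (-0.59 ± 0.27) and the calcium-binding chaperone Calr (-0.44 ± 0.14). In the SY mice alone this list did not pass (adjusted p = 0.144).

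Markers of macrophages and of stellate cells, the matrix-producing cells of the liver, lay on the Gstm1 side as lists, but not every marker did. Of 16 Kupffer cell and macrophage genes 11 were negative and 1 positive, also when adjusted over the list alone (median -0.18, adjusted p = 0.00752; adjusted p = 0.657 with an estimated correlation). The negative ones included the lysosomal protein Cd68 (-0.65 ± 0.22), the lectin Lgals3 (-0.58 ± 0.32) and the protease Ctss (-0.38 ± 0.26), and the positive one was the myeloid factor Spi1 (0.28 ± 0.10). Marco (-0.16), Clec4f (-0.05), Adgre1 (-0.03) and Ccr2 (0.04) were not called. In the TP mice alone the list did not pass (adjusted p = 0.289). Of 15 stellate cell and fibroblast genes 10 were negative and 0 positive, also when adjusted over the list alone (median -0.20, adjusted p = 0.00374; adjusted p = 0.671 with an estimated correlation). The negative genes included smooth muscle actin Acta2 (-0.49 ± 0.28) and the collagens Col4a1 (-0.46 ± 0.17), Col4a2 (-0.34 ± 0.20) and Col1a1 (-0.31 ± 0.28). All 5 actins measured were negative, and the probe of Acta2 can also bind the transcripts of other actins. Dcn (-0.11), Timp1 (-0.05), Tagln (-0.05), Des (-0.04) and Reln (-0.01) were not called. The remaining cell type lists did not pass. Lymphocyte genes had 7 of 12 negative, led by Cd52 (-0.40 ± 0.19), and 1 positive (adjusted p = 0.265), and neutrophil genes 3 of 6 negative (adjusted p = 0.469). Endothelial genes had 2 of 9 negative, led by Eng (-0.29 ± 0.07), and 1 positive (adjusted p = 0.635). Bile duct genes had 3 of 9 negative, led by Epcam (-0.42 ± 0.24), and 1 positive (adjusted p = 0.454). Pancreatic acinar genes had 2 of 7 negative and 2 positive (adjusted p = 0.984), and adipocyte genes 2 of 5 negative (adjusted p = 0.535). Their counts adjusted over the list alone were the same. Male-biased and erythroid genes had 3 measured members each and were not tested. Of the former, Cyp2d9 was at 0.29 ± 0.17. Of the latter, Alas2 was at -0.06 and Car2 at -0.03, neither called. In all, 11 of 33 lists passed, 5 positive and 6 negative, and 0 with an estimated correlation. That correlation was estimated without a term for the identifier series, so differences between SY and TP mice entered it. How far this moved the list results was not tested.

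**Figure D2:**
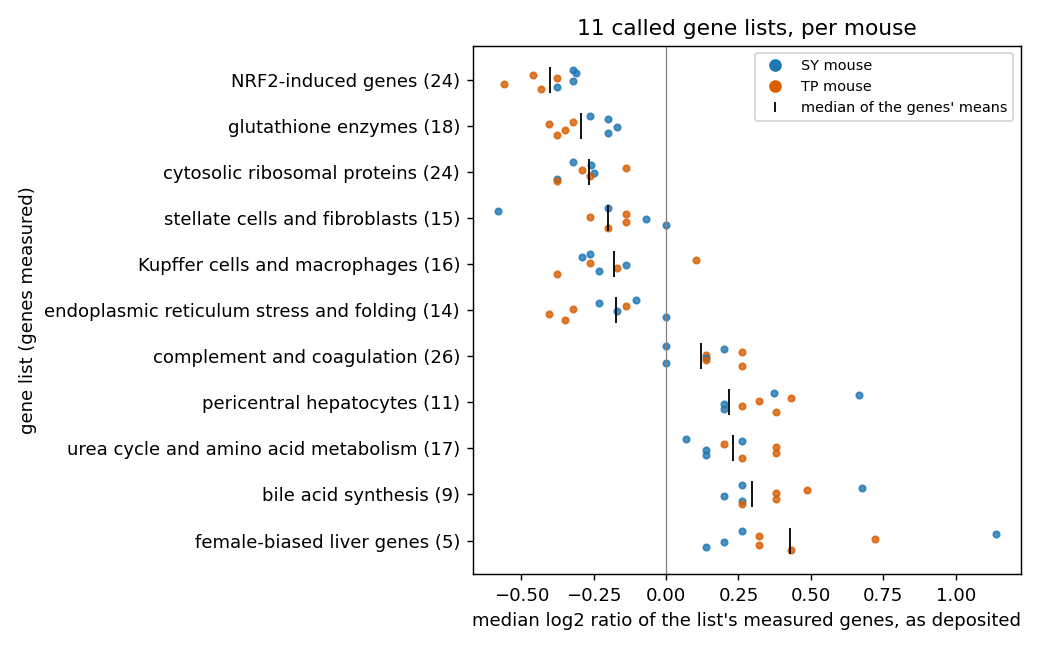
Median deposited log2 ratio (x axis) of the measured genes of the 11 called gene lists (y axis, with the number of genes); points are the 8 mice, coloured by identifier series, and black ticks are medians of the genes' means. The NRF2 list had a median of -0.40 and bile acid synthesis 0.30.

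The mouse identifiers fall into 2 series, SY and TP, 4 mice each, whose meaning no label states, and array codes nearly follow them: c3z for SY and bl7 for TP, except SY518Z with 1 array of each. The urea cycle enzyme Cps1 averaged -0.10 in SY and 0.70 in TP mice (limma, adjusted p = 0.00413), and the aminotransferase Got1 differed by -0.87 (SY minus TP, adjusted p = 0.00892). Higher and lower refer here to the deposited ratio, and would turn if its direction were turned. The leptin receptor Lepr (-0.76), Tdp1 (-0.64) and Zic1 (-1.38) were also lower in SY, while the peroxisomal transferase Crot (0.83), Qser1 (0.69), the mitochondrial protease Clpx (0.62), S100a10 (0.61) and the claudin Cldn4 (0.60) were higher. Cldn4 lost its call when any 1 mouse but SY518Z was left out (adjusted p 0.0637 to 0.145), and Qser1 when any 1 but SY518Z or TP4163 was (0.0556 to 0.102). Clpx did not pass without SY521RL, TP4215, SY524ROB+L, TP4205 or SY522ROB (0.0626 to 0.11), nor Lepr without SY524ROB+L, TP4205 or SY522ROB (0.0588 to 0.0655). In all 476 of 8348 differed, 108 above and 368 below in SY, and 2067 at an unadjusted p under 0.05. The count was 1278 without SY518Z, 55 without SY521RL, 180 without TP4215, 188 without TP4168, 56 without SY524ROB+L, 76 without TP4205 and 60 without SY522ROB. Of the 3622 genes called for the diet, 179 also differed between the series, against 476 of all 8348, and 7 had SY and TP means of opposite sign. A difference between the series adds to the spread among mice and works against a diet call. Both counts are therefore held down by the selection and do not measure agreement between the series. The diet count was 2159 in SY and 3168 in TP mice.

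**Figure D3:**
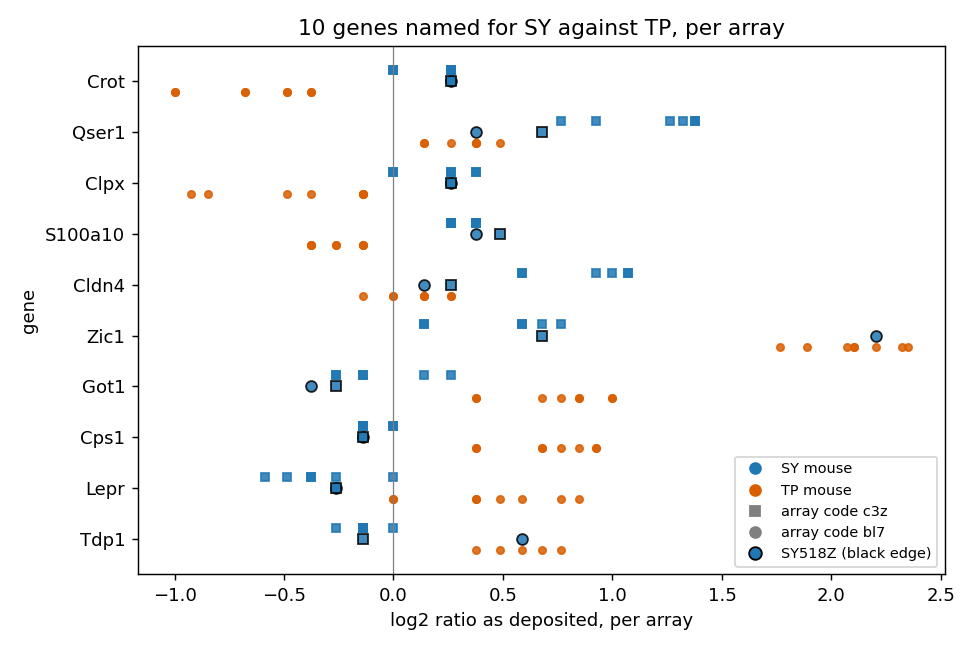
Deposited log2 ratio of each array (x axis) for the 10 genes named for SY against TP (y axis); colour is the identifier series, squares and circles the array codes, and black edges mark SY518Z. Its bl7 array read 2.20 for Zic1 and its c3z array 0.68, while both arrays read -0.14 for Cps1.

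The 2 arrays of a mouse, carrying the same RNA, correlated across genes with a median Pearson r of 0.878 (0.759 in SY518Z to 0.913), against 0.579 between arrays of different mice. Genes are not independent replicates, and no test was made. Between different mice r was 0.706 within a series and 0.553 between SY and TP.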

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

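The tests of hepatocyte share, abundant transcripts and dye effects were chosen only after the result was seen. The test of array codes was written before its value was known but after the count of 1278 genes without SY518Z had been seen.

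SY and TP mice differed in 476 genes. Of the 35 splits of the 8 mice into 4 and 4, only 1, the real one, gave as many, and the highest of the others gave 1. No split can be rarer than 1 in 35, so this does not exclude chance. The real split also nearly follows the array codes, which every other split mixes within its groups. Over the genes that differed between the other 3 SY mice and the TP mice, the c3z array of SY518Z minus its bl7 array, both of the same RNA, showed a median of 0.507 of the difference (bootstrap interval over genes 0.485 to 0.531 around a bound of 0.5), against 0 for the other 7 mice. The interval resamples genes read on 1 pair of arrays. It does not measure how an effect of the array code would vary between mice. Of 1196 such genes, 461 had the bl7 array nearer TP and the c3z array nearer SY, 176 had both arrays nearer SY, 531 both nearer TP, and 28 the reverse. Of the 10 genes named for this comparison, 2 followed the code in that way (Zic1 and Tdp1), 6 had both arrays nearer SY (Crot, Clpx, S100a10, Got1, Cps1 and Lepr) and 2 both nearer TP (Qser1 and Cldn4). These 10 were ranked with SY518Z counted as SY, which favours genes with both its arrays near SY, so their counts carry no weight here. Over the genes called without SY518Z, its bl7 array lay at a median of 0.058 between TP (0) and SY (1). Its c3z array lay at 0.60. On code bl7 this SY mouse thus lay near the TP mice over these genes, and on c3z partway to the other SY mice. The gap that its c3z array leaves is within 1 series and 1 code. These genes were picked for a difference without SY518Z, which can widen that gap. The array code may account for part of the difference between the series. With 1 mouse carrying both codes, its share and that of the series cannot be told. A biological difference between the series was not tested, since no label says what they are.

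Macrophage, stellate cell and ribosomal genes lay on the Gstm1 side as lists. None of these lists passed with an estimated correlation (camera, adjusted p = 0.657, 0.671 and 0.458), and the macrophage list did not pass in TP mice alone (0.289). The test assumed that a lower share of hepatocytes in 1 channel would shift all other cell types alike. Rounded values and unequal changes of the cell types could depart from this. A difference between the lists could therefore not have excluded a lower share either. The 6 fixed lists of other liver cell types had means of -0.21 (stellate), -0.20 (Kupffer), -0.18 (neutrophil), -0.09 (lymphocyte), -0.07 (bile duct) and -0.06 (endothelial). These did not differ by more than the spread among their 67 genes (permutation test of the F statistic, p = 0.23), which neither excludes nor shows a lower share, so it stays open. A bias against abundant transcripts is argued against only for 13 abundant hepatocyte transcripts, whose median was 0.0894. Of these, 4 were positive, 2 negative (Apoa1 at -0.52 and Trf at -0.41) and 7 not called. The 24 ribosomal proteins had -0.27 (permutation p = 2e-04), but they are part of the pattern itself, and genes are not independent replicates. Signal strength was not analysed here, so such a bias in other abundant transcripts stays open. A dye effect specific to each gene could not be tested, with 0 arrays of swapped dyes, and stays open. A change in macrophages or stellate cells themselves was not tested.

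Single mice stood far from the others in 6 of 172 results tested, where chance alone flags about 1 in 20. SY518Z had 0.85 for Amacr (nearest mouse 0.49), 0.26 for Cyp2f2 (nearest -0.54), a median of 0.32 for PXR and CAR-induced genes (nearest 0.10) and -0.58 for stellate cell genes (nearest -0.26). Mouse TP4163 had -0.0688 for Egfl7 (nearest 0.0688), and TP4215 a median of -0.10 for cholesterol synthesis genes (nearest 0).

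Among named genes 23 differed between SY and TP. SY minus TP was -1.38 for Zic1, -0.87 for Got1, -0.80 for Cps1, -0.76 for Lepr, -0.64 for Tdp1, -0.56 for Fmo5, -0.51 for Try4, -0.36 for Abcg1, -0.32 for Usp2 and -0.31 for Ugp2. It was 0.27 for Nqo1, P4hb and Jchain, 0.28 for Mttp, 0.31 for Gstm6, 0.47 for Hal, 0.48 for Gstm2, 0.56 for Ehhadh, 0.60 for Cldn4, 0.61 for S100a10, 0.62 for Clpx, 0.69 for Qser1 and 0.83 for Crot.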

How the results depend on the processing

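The settings chosen only after the result was seen were the control RNA as a mix of varying mice, the arrays scaled to a common SD and the loss of the second array of TP4205. The 3622 diet genes became 2159 in SY mice alone (3168 in TP mice alone, also 4 mice; the cause was not tested), 123 when tested against a fold of 1.2, 63 when 1.5-fold was also required, 2387 at an adjusted p under 0.01 and 1805 (731 positive, 1074 negative) with the control as a mix of 7 mice, whose standard error was 1.46 times larger. Without single mice the count was 3038 to 3776, and under the other settings it was 3043 to 4165. No named gene or list turned its sign where it passed the test in either setting. Among those that passed in neither, 10 turned, and the cause was not tested. In SY mice alone these were Mttp (0.017) and the medians of bile acid and sterol transport (0.0295), FXR-induced (0.047), AHR-induced (-0.033), oxidative phosphorylation (0.00075), proteasome (0.0071), heat shock (-0.069) and periportal genes (-0.108). PXR and CAR-induced genes had -0.034 in TP mice alone, periportal genes -0.042 with the looser filter on blanks, and AHR-induced genes -0.026 on complete rows. Without single mice fatty acid synthesis ran from -0.014 (without TP4163) to 0.082, and heat shock genes from -0.064 (without TP4168; -0.027 without TP4163) to 0.164. Median centring and limma's scale normalization moved nothing, because every array already had a median of 0 and a median absolute value of 0.138, the smallest step of the rounding, and so say nothing about stability. Of 131 diet genes named, 43 lost their call with the mix of control mice, 44 in SY mice alone and 25 in TP mice alone. The 11 lists called became 0 with an estimated correlation and 19 with fry, which does not compare a list with other genes; the others gave 9 to 12. The 476 genes between SY and TP ran from 55 (without SY521RL) to 1278 (without SY518Z, 667 above and 611 below in SY), with 180, 188, 56, 76 and 60 without TP4215, TP4168, SY524ROB+L, TP4205 and SY522ROB; the cause was not tested beyond the array codes. Of the 10 genes named for it, Qser1, Clpx and Cldn4 lost their call with robust moderation (adjusted p 0.063, 0.0585 and 0.0933), and Cldn4 also with values in all 8 mice required (0.0511). The median correlation of 0.878 between arrays of a mouse became 0.632 after each gene was centred on its mean, which removes what all arrays share, and 0.831 as Spearman rho. Rounding to 1 decimal limits differences smaller than 0.138 on the log2 scale, and signal over background was not analysed here.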

Other observations

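The tests on gene families in this part were chosen only after the result was seen. Of 8 families picked by name, actins, translation elongation factors and the Cyp2c subfamily passed camera, and 0 did with an estimated correlation. The 5 actins were negative (median -0.57; camera, adjusted p = 0.000872; adjusted p = 0.307 with an estimated correlation), led by Actb at -0.78 ± 0.22 (SD, n = 8; limma, adjusted p = 5.14e-06), although actin cDNAs are so alike that 1 transcript can bind several probes. Among the tubulins 3 of 5 were negative, such as Tubb4b (-0.59 ± 0.30), 1 was positive, Tubb4a (0.20 ± 0.15), and Tubb2b (-0.12) was not called (camera, adjusted p = 0.168). Of the actin-binding thymosins, profilins and cofilins, Tmsb4x (-0.73 ± 0.20) and Cfl2 (-0.24 ± 0.10) were negative and Pfn2 (0.11) was not called (camera, adjusted p = 0.168). Of 9 annexins, membrane-binding proteins, 5 were negative, led by Anxa5 (-0.62 ± 0.36), and 1 positive (camera, adjusted p = 0.116). Among translation elongation factors Eef1g (-0.57 ± 0.15), Eef1a1 (-0.40 ± 0.16) and Eef2 (-0.34 ± 0.14) were negative, and Eef1a2 (0.04) was not called (camera, adjusted p = 0.0301; adjusted p = 0.307 with an estimated correlation).

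The antigen-presenting gene H2-Aa was at -0.64 ± 0.29 and H2-Ea at -0.25 ± 0.06, while 4 of 6 members of that group, the invariant chain Cd74 (-0.05 ± 0.24) among them, were not called (camera, adjusted p = 0.173). On the Cyp7a1 side lay Cyp2c69 (0.61 ± 0.15) and Cyp2c68 (0.57 ± 0.35), of 3 members of that cytochrome subfamily, which share much of their sequence, while Cyp2c65 (0.049) was not called (camera, adjusted p = 0.0301; adjusted p = 0.307 with an estimated correlation). Of 7 S100 proteins 2 were negative, 1 positive and 4 not called (camera, adjusted p = 0.967). The plasma protein Trf, which carries iron, was at -0.41 ± 0.18 and the retinol carrier Rbp4 at 0.19 ± 0.12.

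Cyp3a11 had values only on arrays of code bl7: -0.43, -0.26, -0.43 and -0.49 in the TP mice and 0.38 in SY518Z. Of all probes, 260 were blank on all 7 c3z arrays, 206 of which had a value on all 9 bl7 arrays, and 318 were blank on all bl7 arrays, 255 of which had a value on all c3z arrays.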
